A study of Homo sapiens with 21 samples.

How the data were processed

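The series holds RNA-seq of 21 human cell line libraries. Per the labels, RNA was extracted with a kit that keeps small RNA, mRNA libraries were made with an Illumina TruSeq kit, and the tolerant cells were made by 14 days with 40 nM gefitinib or 20 nM osimertinib. Per the labels, overexpression was by lentivirus with puromycin selection, and how the miRNAs were knocked down is not given in the sources used here. Groups were taken from the labels, with 1 library for each condition and line: PC9 and HCC827 are replicates 1 and 2 of the tolerance groups, AALE, HCC827 and PC9 replicates 1, 2 and 3 of the overexpression groups, and H1975 and PC9ER replicates 1 and 2 of the knockdown groups. Nothing says that libraries came from separate cultures of a line, so the cell lines are the replicates and p-values measure the spread between these samples alone, which may be technical in part.

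The authors deposited expected counts per gene in 3 tables and a summary of read counts per library. Per the submitters' processing notes the expected counts were made with Bowtie2 and RSEM on GRCh37, and the tool versions and the annotation release are not given in the sources used here. The deposited summary gives counts of reads, 17932024 to 33129732 per library with a median of 24566180. The percent of bases of quality 30 or more was 96.4 to 97.1 in the deposited summary. Dividing its yield by its reads gives reads of 50 bases. The expected counts summed to 15516460 to 29694050 per library (median 22026253), 85.4% to 91.2% of reads. Of the nonzero expected counts, 64.3% were not whole, and all were rounded to whole numbers before testing. The tables hold 56632 Ensembl genes, 4916 symbols are used more than once, so genes were matched by identifier, 0 entries name no gene and 0 columns were left unmapped. The 5 control columns that both miRNA tables share held identical values, so these tables were joined by gene. The file of 1 table is named for another miRNA than its columns, and the column names, which match the labels, were used. Of 210 pairs of libraries 0 were identical.

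Libraries were scaled by TMM, low counts were filtered with filterByExpr over the groups of a fit, and genes were tested by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, version 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The 11 contrasts were gefitinib tolerance, osimertinib tolerance, osimertinib against gefitinib, the mean of both drugs, tolerance by cell line (an interaction with both drugs as repeats), overexpression and knockdown of each miRNA, and overexpression minus knockdown of each miRNA. The 6 tolerance, 9 overexpression and 6 knockdown libraries were fitted apart, and the last 2 contrasts in a fit of all 15 miRNA libraries. The cell line was a block in every fit. The pairing comes from the labels, and after centring each group, libraries of the same line correlated at 0.706 to 0.859 in tolerance, 0.904 to 0.923 in overexpression and 0.797 to 0.93 in knockdown.

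Of 29 gene lists, 28 had at least 5 tested members and were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation and fry beside it. The other, miR-147b targets of interest, holds VHL and SDHD, whose values are given as genes. Lists covered signalling and metabolic pathways, the cell cycle, histones, ribosomal and mitochondrial genes, reported miR-21 targets, and markers of other cell types, namely mesenchymal, epithelial, alveolar and airway, basal and squamous, neuroendocrine, leukocyte and fibroblast markers. They were written from general knowledge, not from these libraries. Of the 88 lists called over the 11 contrasts, 0 differed in the sign of median, mean and test, and of the 220 not called, 38 did. With an estimated correlation 0 lists were called, and fry called 4. For single pairs of libraries, list medians were computed with a prior count of 2 and placed among 10000 random lists matched on mean expression. Named genes were, per contrast, the 10 largest changes in each direction among those that passed with the same sign in every line and a mean of at least 1 log2 CPM, or, where fewer than 10 passed, all that passed and then the smallest p with the same sign up to 5 per direction. To these were added EGFR, VHL, SDHD, MIR147B, MIR21 and VMP1, up to 4 members of each list that passed or 2 that came nearest, and for single pairs up to 5 genes per direction with at least 10 CPM in 1 of the libraries. A few of the genes that the rule gives are printed, 1 that it gives is not reported here, and genes outside it are said to be so. The groups, tests, gene lists, rule and main alternatives were fixed before the data were examined.

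GENCODE release 29 on GRCh38 gave coordinates, gene lengths, GC content and 3' UTRs, since the build the authors used was not among the references used here, and 95.3% of protein-coding genes had a length and 90.0% a 3' UTR (18395 of 20428). Seed sites were matches of CCGCACA for miR-147b and ATAAGCT for miR-21 in 3' UTRs. For contrasts with shared controls, 20 simulations of unchanged groups gave the correlation and covariance that the controls alone produce. A count of 0 was given a floor of 3 counts per library, and reads amplified by PCR without molecular identifiers are not independent molecules, so floors cover counting error only. The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in the same edgeR fit, no filter on low counts, no block, each library or line left out, all 15 miRNA libraries in 1 fit, 50 or 200 tolerance genes per direction, 8mer and matched seed sites and, added later, limma voom, a length and GC correction, and fits without mitochondrially encoded genes, pseudogenes or small noncoding RNA genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

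The tests were tested on simulated data with 200 single genes changed, and 25 more raised by 1 log2 as a set, among the real means and library sizes. Counts were drawn at the fitted spread of each gene, and the changed genes all had a mean over 2 log2 CPM. Shares recovered from such counts may exceed those in the real libraries, where 0 genes passed for gefitinib tolerance. The fit called 130 genes for gefitinib tolerance (20 false), 96 for tolerance by cell line (11 false), 218 for miR-147b overexpression (9 false), 96 for miR-147b knockdown (6 false) and 194 for miR-147b overexpression minus knockdown (13 false). Changes of log2 size 1, 2 and 4 were recovered at 4.5%, 61.2% and 98.5% for gefitinib tolerance, 0%, 41.8% and 84.8% for tolerance by cell line, 82.1%, 97.0% and 100% for miR-147b overexpression, 3.0%, 35.8% and 97.0% for miR-147b knockdown, and 58.2%, 98.5% and 100% for miR-147b overexpression minus knockdown. Camera called the raised set in each, and 0 of 19 unchanged sets. These sets were random genes drawn independently, so they do not test camera on lists whose genes move together.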

Results

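Polyadenylated RNA from 5 human cell lines was sequenced in 21 libraries that fall into 9 groups, with 1 library for each condition and cell line. PC9 and HCC827 are lung adenocarcinoma lines with activating EGFR mutations, AALE is an immortalized airway epithelial line, and H1975 and PC9ER are lung adenocarcinoma lines labelled as carrying the gatekeeper resistance mutation of EGFR. The 6 tolerance libraries hold parental, gefitinib-tolerant and osimertinib-tolerant cells of PC9 and HCC827 (n = 2 lines per group), the drugs having been given for 14 days at 40 nM gefitinib or 20 nM osimertinib. The 9 overexpression libraries hold AALE, HCC827 and PC9 carrying a scrambled control, miR-147b or miR-21 (n = 3 lines per group), and the 6 knockdown libraries hold H1975 and PC9ER with a control, miR-147b or miR-21 knockdown (n = 2 lines per group). Expected counts summed to between 18891000 and 26972727 in the tolerance libraries, 16679299 and 29694050 in the overexpression libraries and 15516460 and 23680635 in the knockdown libraries. The cell lines served as the replicates and as a block in each fit, and levels are given as CPM, counts scaled to the library size, of single libraries.

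Gefitinib-tolerant cells were compared with their parental lines to ask what distinguishes cells that persist under a reversible EGFR inhibitor. The labels give no drug dose for parental cells, so tolerance and the 14 days of drug cannot be told apart in comparisons with them. Cell cycle genes had lower and replication-dependent histones higher medians in both lines. TP53INP1, a stress-induced regulator of autophagy and cell death, stood at 0.28 CPM in parental and 7.71 in gefitinib-tolerant PC9, and at 7.69 and 139 CPM in HCC827, a log2 fold change of 4.36 ± 0.31 (SE, n = 2 lines). PIK3IP1, a negative regulator of PI3K, was higher by 4.46 ± 0.33, and VTCN1, an inhibitory ligand of T cells also called B7-H4, by 5.28 ± 0.42 (log2, SE, n = 2). SRM, the polyamine enzyme spermidine synthase, was at 291 CPM in parental and 68.3 in tolerant PC9 and at 263 and 65.2 CPM in HCC827, with a log2 fold change of -2.05 ± 0.22, and the ribosome biogenesis factor BOP1 had -1.96 ± 0.22. The AP-1 subunit FOSL1, the lipid enzyme AGPAT9 and the integrin ITGA6 had -2.18 ± 0.28, -3.25 ± 0.31 and -2.41 ± 0.28.

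Gene groups moved together in the gefitinib-tolerant libraries. All 25 G2/M and mitosis genes were lower, at a median log2 fold change of -2.47, and all 25 DNA replication and S phase genes at -1.79. Of these, 23 and 22 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.29e-18 for both, and adjusted p = 0.820 with an estimated correlation). CENPE, a kinetochore motor, had -1.43 ± 0.26 and RRM1, the large subunit of ribonucleotide reductase, -1.62 ± 0.33. Basal and squamous markers were lower in 17 of 23 genes (median -2.15, 10 passing adjusted over the list alone, camera adjusted p = 3.6e-10, adjusted p = 0.281 with an estimated correlation). Replication-dependent histones were higher in 16 of 18 genes (median 1.77, 10 passing adjusted over the list alone, camera adjusted p = 9.6e-10, adjusted p = 0.281 with an estimated correlation). HIST1H1C and HIST1H2BD had 1.86 ± 0.28 and 2.0 ± 0.30. Histone genes are near-identical copies that share reads, so values of single members are uncertain. YAP/TEAD target genes were higher in 17 of 21 genes (median 0.92, camera adjusted p = 3.93e-05) and glycolysis enzymes and transporters lower in 18 of 20 (median -1.16, camera adjusted p = 3.95e-05), with adjusted p = 0.820 for both with an estimated correlation. ENO1, a glycolytic enolase, had -1.31 ± 0.37. Type I interferon response genes were lower in 26 of 30 (median -0.68, camera adjusted p = 0.00776, adjusted p = 0.870 with an estimated correlation). TCA cycle enzymes were lower in 15 of 20 (median -0.39, camera adjusted p = 0.0163, adjusted p = 0.829 with an estimated correlation). The glycolysis median was -0.18 in PC9, with 11 of 20 lower, and -1.93 in HCC827, with 19 of 20 lower. The interferon median was 0.38 in PC9 and -1.50 in HCC827, and it turned to 0.37 without the parental HCC827 library. The stress gene GADD45B had 2.43 ± 0.28 and HLA-DMA, a chaperone of MHC class II peptide loading, 2.27 ± 0.37, and HLA genes share reads with their paralogs.

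EGFR itself had a log2 fold change of -0.56 ± 0.23 with gefitinib tolerance, VMP1, whose span holds MIR21, 1.10 ± 0.24, VHL 0.23 ± 0.26 and SDHD -0.10 ± 0.24 (SE, n = 2 lines). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 19837 genes passed, with 3469 at an unadjusted p under 0.05 and a smallest adjusted p of 0.211, so the gene values above are values and not calls. DESeq2's Wald test called 1346 genes (658 higher and 688 lower) and limma voom 0. Without the parental PC9 library the edgeR fit called 3571 genes, without the osimertinib-tolerant PC9 library 10, without the osimertinib-tolerant HCC827 library 9, and with no filter on low counts 47.

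**Figure D1:**
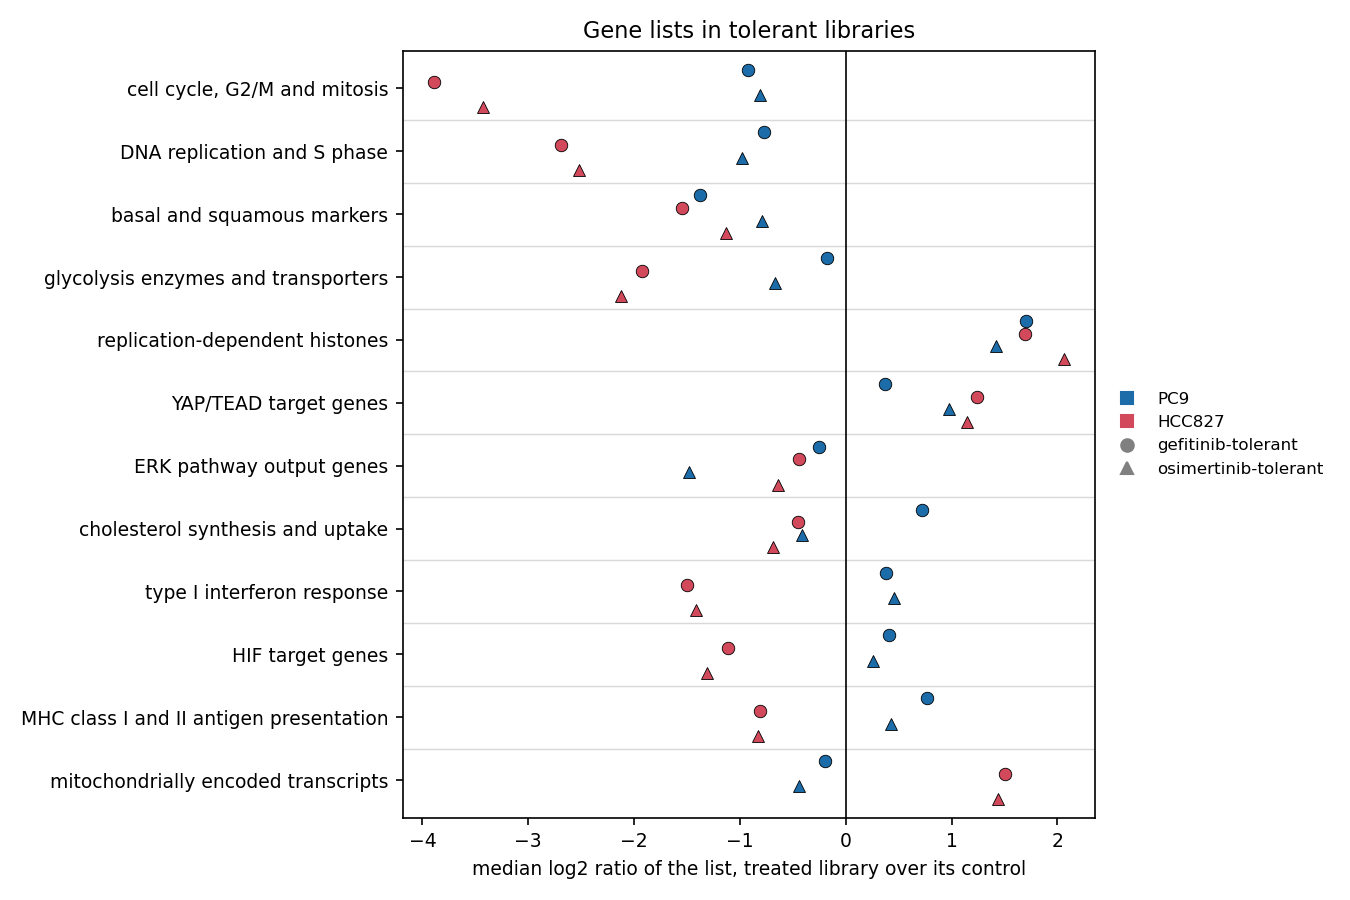
Median log2 ratio of each of 12 gene lists (y axis) in each tolerant library over the parental library of its line, with PC9 in blue, HCC827 in red, gefitinib as circles and osimertinib as triangles; each point is 1 library pair. The G2/M list lies at -3.89 and -3.42 in HCC827 against -0.93 and -0.81 in PC9, and the histone list between 1.42 and 2.06 in all 4 pairs.

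Osimertinib, a covalent inhibitor of mutant EGFR, was compared with the parental lines in the same way. The leading genes included TP53INP1 at a log2 fold change of 4.60 ± 0.31, PIK3IP1 at 4.50 ± 0.33, VTCN1 at 5.84 ± 0.43 and the transcription cofactor LBH at 5.41 ± 0.39 (SE, n = 2 lines). CDKN2B, the CDK4/6 inhibitor p15, was at 3.93 CPM in parental and 49.8 in tolerant PC9 and at 9.40 and 192 CPM in HCC827, a log2 fold change of 4.0 ± 0.31. SRM, BOP1, AGPAT9, ITGA6 and FOSL1 had -2.29 ± 0.22, -2.23 ± 0.22, -3.04 ± 0.31, -2.69 ± 0.28 and -2.68 ± 0.28. All 25 S phase genes (median -1.81, 22 passing adjusted over the list alone, camera adjusted p = 5.19e-15) and all 25 G2/M genes (median -2.30, 0 passing adjusted over the list alone, camera adjusted p = 4.13e-13) were lower, with adjusted p = 0.703 and 0.711 with an estimated correlation. CENPE and RRM1 had -1.16 ± 0.26 and -1.58 ± 0.33. ERK pathway output genes were lower in 16 of 20 (median -0.99, 2 passing adjusted over the list alone, camera adjusted p = 4.31e-05, adjusted p = 0.703 with an estimated correlation). PHLDA1 had -2.31 ± 0.40. Mesenchymal markers were higher in 16 of 24 (median 1.11, camera adjusted p = 0.0344, adjusted p = 0.793 with an estimated correlation). The fibrillar collagen COL5A1 and fibronectin, FN1, had 2.57 ± 0.43 and 1.65 ± 0.35.

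Further lists were called with osimertinib tolerance. Histones were higher in a median of 1.84 (10 passing adjusted over the list alone, camera adjusted p = 8.53e-09, adjusted p = 0.617 with an estimated correlation). HIST1H1C and HIST1H2BD had 2.20 ± 0.28 and 2.15 ± 0.30. YAP/TEAD target genes were higher in 18 of 21 (median 1.01, camera adjusted p = 1.4e-06), basal markers lower in 18 of 23 (median -1.74, camera adjusted p = 1.29e-07) and glycolysis genes lower in 18 of 20 (median -1.49, camera adjusted p = 1.29e-07), each with adjusted p = 0.703 with an estimated correlation. ENO1 and the hexokinase HK2 had -1.80 ± 0.37 and -2.20 ± 0.58. TCA cycle enzymes (17 of 20 lower, median -0.50, camera adjusted p = 0.00137) had adjusted p = 0.733 with an estimated correlation. Lower medians with camera adjusted p from 0.00299 to 0.022, and adjusted p = 0.793 with an estimated correlation, were found for cytoplasmic ribosomal proteins (54 of 72, -0.24), cholesterol synthesis and uptake (22 of 25, -0.64), the nuclear-encoded respiratory chain (25 of 32, -0.36) and HIF target genes (21 of 29, -0.78). The HIF median was 0.26 in PC9 and -1.31 in HCC827 and became 0.23 without the parental HCC827 library. GADD45B had 2.83 ± 0.29, EGFR -0.82 ± 0.23, VMP1 1.27 ± 0.25, VHL -0.24 ± 0.26 and SDHD -0.27 ± 0.24. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 19837 genes passed, with 3922 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152. DESeq2 called 1761 genes (814 higher and 947 lower) and limma voom 0. edgeR called 137 with no filter on low counts, 3976 without the parental PC9 library, 8 without the parental HCC827 library, 76 without the gefitinib-tolerant HCC827 library and 3 without the osimertinib-tolerant PC9 library.

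The fold changes of both drugs correlated across genes with r = 0.899, against 0.501 in simulated groups that shared the parental controls without any effect, and their covariance was 0.799 against a simulated 0.145. The sign was shared by 89.7% of 14207 genes against a simulated 66.5%. Each line has 1 parental library, which cannot be split, so part of the excess may come from the shared controls, and genes are not independent replicates. In the mean of both drugs, TP53INP1, PIK3IP1, VTCN1 and LBH had log2 fold changes of 4.48 ± 0.30, 4.48 ± 0.32, 5.56 ± 0.41 and 4.82 ± 0.37 (SE, n = 2 lines), and AGPAT9, SRM, BOP1, ITGA6 and FOSL1 had -3.15 ± 0.24, -2.17 ± 0.18, -2.09 ± 0.18, -2.55 ± 0.22 and -2.43 ± 0.22. EGFR had -0.69 ± 0.19, VMP1 1.19 ± 0.22, VHL -0.01 ± 0.23 and SDHD -0.18 ± 0.20. Of 28 lists, 9 were called, namely S phase (median -1.80), G2/M (-2.34), basal markers (-1.84), histones (1.84), glycolysis (-1.33), YAP/TEAD targets (0.97), ERK output (-0.85), TCA cycle (-0.45) and interferon (-0.64), with camera adjusted p from 8.35e-19 to 0.0242 and adjusted p from 0.296 to 0.844 with an estimated correlation. The interferon median turned to 0.39 without the parental HCC827 library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 19837 genes passed, with 4650 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. DESeq2 called 2478 genes (1164 higher and 1314 lower), limma voom 0 and edgeR with no filter on low counts 541. Leaving out the parental PC9, gefitinib-tolerant PC9, osimertinib-tolerant PC9, parental HCC827, gefitinib-tolerant HCC827 or osimertinib-tolerant HCC827 library gave 4584, 2, 31, 19, 10 and 28 genes.

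The drugs were then compared directly, at doses that differ. MMP7, a secreted matrix metalloproteinase, was at 62.3 CPM in gefitinib-tolerant and 4.80 in osimertinib-tolerant PC9 and at 11.5 and 1.36 CPM in HCC827, a log2 difference of -3.40 ± 0.32 (osimertinib minus gefitinib, SE, n = 2 lines). PI3, the elastase inhibitor elafin, had -3.61 ± 0.58, SOD2, the mitochondrial superoxide dismutase, -2.19 ± 0.39, the actin regulator CYFIP2 -2.27 ± 0.36 and the interleukin-1 receptor kinase IRAK2 -1.35 ± 0.26. Higher values were found for the sphingosine-1-phosphate receptor S1PR3 (1.27 ± 0.26) and KAL1 (1.07 ± 0.25). All 72 cytoplasmic ribosomal protein genes were lower with osimertinib (median -0.32, camera adjusted p = 4.02e-16), as were 23 of 25 cholesterol genes (median -0.80, camera adjusted p = 1.05e-15) and 18 of 20 ERK output genes (median -0.66, camera adjusted p = 1.18e-07), each with adjusted p = 0.794 with an estimated correlation. The squalene epoxidase SQLE had -0.80 ± 0.27, and PHLDA1 and the ERK phosphatase DUSP5 had -1.0 ± 0.38 and -1.13 ± 0.47. The other called lists were glycolysis (20 of 20 lower, -0.32), respiratory chain (32 of 32 lower, -0.15), NF-kB and inflammatory cytokines (17 of 23 lower, -0.21), HIF targets (21 of 29 lower, -0.26), YAP/TEAD targets (15 of 21 higher, 0.17) and G2/M (25 of 25 higher, 0.23), with camera adjusted p from 0.00412 to 0.0487 and adjusted p from 0.794 to 0.799 with an estimated correlation. The HIF, glycolysis and YAP/TEAD medians became 0.31, 0.29 and -0.23 without the gefitinib-tolerant PC9 library. The HIF median became 0.04 without the osimertinib-tolerant HCC827 library, and the G2/M median became -0.47 without the osimertinib-tolerant PC9 library and -0.42 without the gefitinib-tolerant HCC827 library. EGFR had -0.26 ± 0.23, VMP1 0.18 ± 0.24, VHL -0.48 ± 0.27 and SDHD -0.17 ± 0.24. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 19837 genes passed, with 197 at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 7 genes, MMP7, CYFIP2, SOD2 and PI3 among them, and limma voom 0. Without the gefitinib-tolerant or the osimertinib-tolerant HCC827 library edgeR called 3 and 1.

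**Figure D2:**
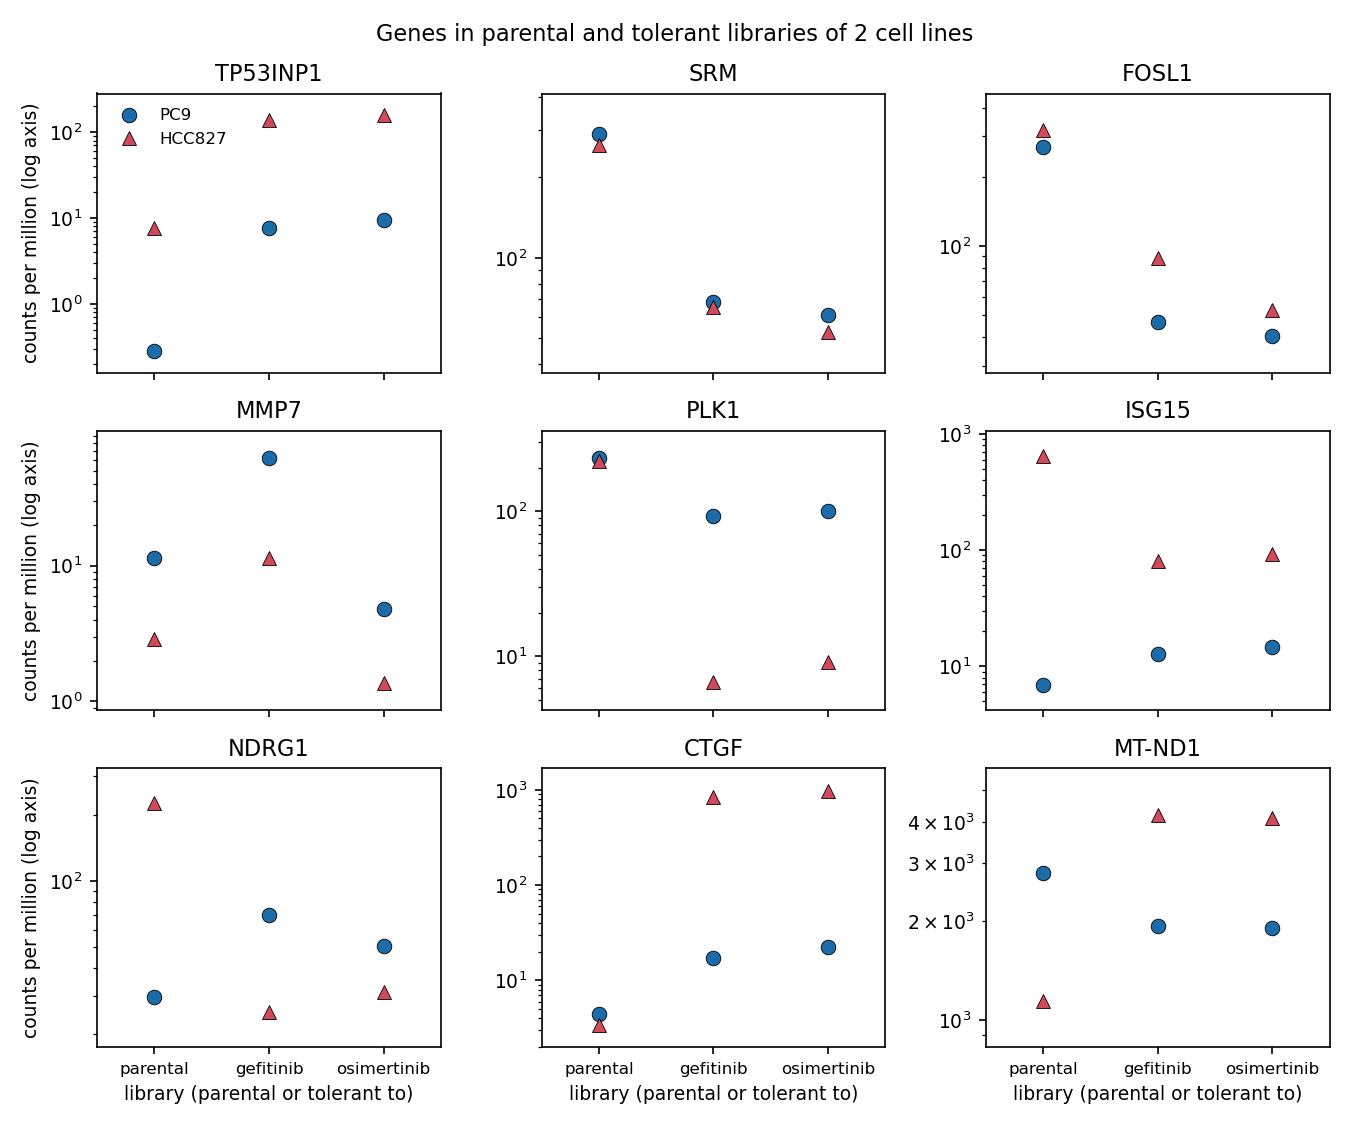
CPM (log axis) of 9 genes in the parental, gefitinib-tolerant and osimertinib-tolerant library of PC9 (blue circles) and HCC827 (red triangles), 1 library per point. TP53INP1 was higher in all 4 tolerant libraries and SRM lower, MMP7 was higher with gefitinib than osimertinib tolerance in both lines, and ISG15 stood at 651 in parental HCC827 against 80.9 and 91.8 in its tolerant libraries.

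The lines were compared in their change with tolerance. The change in HCC827 minus the change in PC9, with both drugs as repeats, passed for 773 of 19837 genes, 380 with higher and 393 with lower values in HCC827 (5318 at an unadjusted p under 0.05). Each line has 1 parental library, so the spread is that between the drugs and the spread of parental libraries was not measured, and edgeR called 0 genes without any 1 of the 4 tolerant libraries and 3 with no filter on low counts. Cell cycle genes were lower in HCC827 by more: PLK1, a mitotic kinase, went from 223 CPM to 6.59 and 9.15 in HCC827 and from 231 to 93.0 and 101 CPM in PC9 (gefitinib and osimertinib), a log2 difference of -3.57 ± 0.33. Interferon genes moved apart: the ubiquitin-like ISG15 was at 651 CPM in parental HCC827 and at 80.9 and 91.8 in the tolerant libraries, and at 6.86, 12.7 and 14.6 CPM in PC9 (-3.90 ± 0.27). Hypoxia genes did so too, the stress gene NDRG1 being at 226, 25.3 and 31.1 CPM in HCC827 and at 29.6, 69.6 and 50.6 in PC9 (-4.03 ± 0.37). CTGF, a secreted YAP target, was at 3.43, 837 and 980 CPM in HCC827 and at 4.42, 17.1 and 22.3 in PC9 (5.90 ± 0.38). These 4 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p of 0.0333, the smallest of the comparison.

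By list, all 25 G2/M genes had lower differences (median -2.83, 17 passing over all genes and 24 adjusted over the list alone, camera adjusted p = 2.95e-31, adjusted p = 0.463 with an estimated correlation). The cyclin CCNB2 and the kinase AURKA had -3.34 ± 0.23 and -3.21 ± 0.25. S phase genes did in 24 of 25 (median -1.63, 15 and 22 passing, camera adjusted p = 4.39e-21, adjusted p = 0.468 with an estimated correlation). The origin licensing factor CDT1 and the helicase subunit MCM4 had -3.71 ± 0.43 and -1.87 ± 0.22. All 30 interferon genes were lower (median -1.83, 15 passing over all genes and 26 adjusted over the list alone, camera adjusted p = 3.1e-23, adjusted p = 0.463 with an estimated correlation). IFIT1 and the signalling factor IRF9 had -3.90 ± 0.36 and -2.91 ± 0.28. HIF targets were lower in 26 of 29 (median -1.18, 9 and 12 passing, camera adjusted p = 5.58e-11, adjusted p = 0.463 with an estimated correlation). Glycolysis genes were lower in 18 of 20 (median -1.91, 5 and 14 passing, camera adjusted p = 1.24e-09, adjusted p = 0.531 with an estimated correlation). BNIP3, a mitophagy receptor, and EGLN3, an oxygen-sensing prolyl hydroxylase, had -2.77 ± 0.20 and -4.41 ± 0.46, and the glycolytic enzymes PGK1 and LDHA -2.67 ± 0.35 and -2.20 ± 0.33. MHC class I and II genes were lower in 18 of 19 (median -1.51, 5 and 9 passing, camera adjusted p = 7.58e-08, adjusted p = 0.463 with an estimated correlation). The immunoproteasome subunit PSMB9 and the peptide transporter TAP1 had -3.02 ± 0.36 and -2.37 ± 0.30.

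All 13 mitochondrially encoded transcripts had higher differences in HCC827 (median 1.73, 7 passing over all genes and 13 adjusted over the list alone, camera adjusted p = 6.1e-15, adjusted p = 0.463 with an estimated correlation). MT-ND3 and MT-ND1 had 3.74 ± 0.42 and 2.41 ± 0.28. Nuclear copies of these genes share their reads, so single members are uncertain. Mitochondrially encoded messages took 1.97% of counts in parental HCC827 and 5.38% and 5.17% in its tolerant libraries, against 3.61%, 3.69% and 3.24% in PC9. Mitochondrial rRNA took 0.806%, 3.955% and 2.82% in HCC827 and 0.479%, 0.787% and 1.22% in PC9, in the same order. Genes annotated as protein-coding took 96.5% of counts in parental HCC827 and 92.7% and 93.8% in its tolerant libraries, so these libraries differ in composition. YAP/TEAD targets were higher in 15 of 21 (median 0.60, 3 and 6 passing, camera adjusted p = 6.96e-05, adjusted p = 0.531 with an estimated correlation), with ANKRD1 at 2.91 ± 0.30 and the angiomotin AMOTL1 at 2.65 ± 0.21. NF-kB genes were higher in 17 of 23 (median 0.79, 2 and 5 passing, camera adjusted p = 0.00261, adjusted p = 0.531 with an estimated correlation). The chemokine CXCL2 and the deubiquitinase TNFAIP3 had 3.47 ± 0.31 and 2.92 ± 0.31. The EGFR ligand HBEGF had 6.61 ± 0.97, and the gelatinase MMP2, at 1.3 CPM or less in parental cells, 4.26 ± 0.58. The epithelial genes MUC1 and CLDN1 parted, at -3.01 ± 0.29 and 2.41 ± 0.26. Epithelial markers (median -0.67), mesenchymal markers (0.74), reported miR-21 targets (0.40), nuclear respiratory chain (-0.23), cholesterol (-1.19), leukocyte markers (-1.95) and NRF2 targets (-0.59) were also called, with camera adjusted p from 0.00921 to 0.0487 and adjusted p from 0.463 to 0.797 with an estimated correlation.

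Among genes with lower differences, TRIM31, a ubiquitin ligase, CYP26A1, a retinoic acid hydroxylase, and MYEOV had -6.87 ± 0.76, -6.81 ± 0.76 and -6.63 ± 0.48. The 10 genes with the highest fitted differences were all at 0 counts in parental HCC827 and 7 of them are annotated pseudogenes, so they are uncertain and no fold is given. Of the 10 lowest, 7 were at or near 0 in parental PC9. EGFR (-0.11 ± 0.35), VMP1 (0.26 ± 0.29), VHL (0.04 ± 0.49) and SDHD (-0.28 ± 0.26) did not pass, at adjusted p of 0.884 for EGFR in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 2347 genes, 757 of them shared, and limma voom 628, 605 of them shared.

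In single pairs of libraries, which carry no test and compare those libraries, the per-pair rule named line- and drug-specific extremes. ALDH1A1, an aldehyde dehydrogenase, was at 0 CPM in parental, 85.1 in gefitinib-tolerant and 1.44 in osimertinib-tolerant HCC827. NUPR1, a stress-induced chromatin protein, was at 0.20 CPM in parental PC9 and at 15.5 and 10.7 in its tolerant libraries, LOXL4, a lysyl oxidase, went from 3.29 to 197 CPM in osimertinib-tolerant PC9, and DUSP6, the ERK phosphatase, from 40.8 to 1.55. KRT6A, an epidermal keratin with near-identical paralogs, went from 620 to 50.4 CPM in gefitinib-tolerant PC9.

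Overexpression of miR-147b was checked on the reads of its own gene. The mature miRNA was not measured in these libraries of polyadenylated RNA. MIR147B (chromosome 15, 45433050 to 45433129, GRCh38), which lies in the last exon of C15orf48, had 526, 386 and 61 counts in the miR-147b libraries of AALE, HCC827 and PC9 and 0 in the other 18 libraries. This is at least 156, 89.9 and 21.2-fold higher than a floor of 3 counts in the control library. MIR147B shares its position with C15orf48, so the allocation of these reads is uncertain, and 0 in the knockdown libraries checks nothing. It was the only gene to pass of 18434, at an adjusted p of 0.0454 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (829 at an unadjusted p under 0.05). MIR21 was at 0 counts in every library, so miR-21 overexpression and knockdown could not be checked on it. VMP1 had 0.17 ± 0.12 with miR-21 overexpression (SE, n = 3 lines) and 0.22 ± 0.25 with its knockdown (SE, n = 2 lines).

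miR-147b overexpression came with higher interferon, inflammatory and squamous genes in AALE and HCC827. All 30 interferon genes had higher values (median log2 fold change 0.84, 20 passing adjusted over the list alone, camera adjusted p = 2.15e-34, adjusted p = 0.430 with an estimated correlation). The median was 1.12 in AALE, 1.01 in HCC827 and 0.09 in PC9. IFI44L was at 52.8 CPM in scrambled and 162 in miR-147b HCC827 (1.67 ± 0.22, SE, n = 3 lines). IFIT1, which binds viral RNA, went from 2.69 to 14.4 CPM in AALE, from 63.0 to 145 in HCC827 and from 0.72 to 1.01 in PC9 (1.56 ± 0.27). NF-kB genes were higher in 22 of 24 (median 0.81, 8 passing adjusted over the list alone, camera adjusted p = 4.14e-12, adjusted p = 0.430 with an estimated correlation). The cytokines IL1A and IL8 had 1.45 ± 0.27 and 1.43 ± 0.27. Basal and squamous markers were higher in 24 of 24 (median 0.55, 3 passing adjusted over the list alone, camera adjusted p = 7.74e-13, adjusted p = 0.430 with an estimated correlation). KRT14, a basal keratin, went from 148 to 694 CPM in AALE, and TP63, the basal transcription factor, from 174 to 295 in AALE and from 3.35 to 19.1 in HCC827. GPCPD1, a phosphodiesterase of choline metabolism, had 0.66 ± 0.11 and S100A8, a calcium-binding alarmin, 0.94 ± 0.17.

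Shifts were also called for 9 other lists with miR-147b overexpression. G2/M genes (median 0.23), HIF targets (0.14), fibroblast markers (0.63), ERK output (0.19) and reported miR-21 targets (0.13) were higher, and ribosomal proteins (-0.11), S phase (-0.14), cholesterol (-0.09) and respiratory chain (-0.05) lower, with camera adjusted p from 2.93e-08 to 0.0371 and adjusted p from 0.430 to 0.553 with an estimated correlation. VHL, which degrades HIF, and SDHD, a subunit of succinate dehydrogenase, the genes of interest as miR-147b targets, had 0.02 ± 0.10 and 0.17 ± 0.12 with overexpression, 0.05 ± 0.32 and 0.03 ± 0.29 with knockdown, and -0.05 ± 0.26 and 0.13 ± 0.26 as the difference between them (log2, SE), all short of the threshold. VHL turned to -0.001 with DESeq2 size factors and -0.002 in DESeq2. EGFR had 0.36 ± 0.28 and VMP1 0.08 ± 0.12. DESeq2 called 7 genes, IFI44L, IL8, IFIT1, GPCPD1 and IL1A among them, with 0 shared with edgeR, and limma voom 4. The edgeR count was 0 without AALE, 5 without PC9, 0 without the block, 0 with all 15 miRNA libraries in 1 fit and 263 with no filter on low counts. EGFR turned to -0.17 without AALE and -0.10 without the block.

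With miR-21 overexpression, SFTPB, a surfactant protein, went from 23.6 to 7.96 CPM in HCC827 (log2 fold change -1.47 ± 0.24, SE, n = 3 lines), and S100A8 and the matrix protein SPP1 had 0.77 ± 0.17 and 0.58 ± 0.14. Epithelial markers were lower in 23 of 25 (median -0.19, camera adjusted p = 3.35e-05) and MHC genes in 17 of 20 (-0.14, camera adjusted p = 0.00551), with adjusted p = 0.808 for both with an estimated correlation. The claudin CLDN3 and the MHC class II activator CIITA had -0.43 ± 0.23 and -0.53 ± 0.24. Cholesterol genes were lower (median -0.06, camera adjusted p = 0.00271) and HIF targets (0.07, camera adjusted p = 0.0073) and ribosomal proteins (0.02, camera adjusted p = 0.0277) higher, with adjusted p from 0.808 to 0.833 with an estimated correlation. The HIF median turned to -0.004 without HCC827 and the ribosomal median to -0.07 without AALE and -0.01 with no filter on low counts. Reported miR-21 targets were not called, with medians of 0.02 on overexpression (camera adjusted p = 0.474) and 0.11 on knockdown (camera adjusted p = 0.528). EGFR had -0.02 ± 0.27, VHL -0.03 ± 0.10 and SDHD 0.14 ± 0.12. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 18434 genes passed (172 at an unadjusted p under 0.05, smallest adjusted p 1). DESeq2 called 1, limma voom 0 and edgeR with no filter on low counts 76. The fold changes of miR-147b and miR-21 overexpression correlated across genes with r = 0.41, against 0.495 in simulated unchanged groups with the same controls, and the covariance differed from the simulated one by -0.0071.

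**Figure D3:**
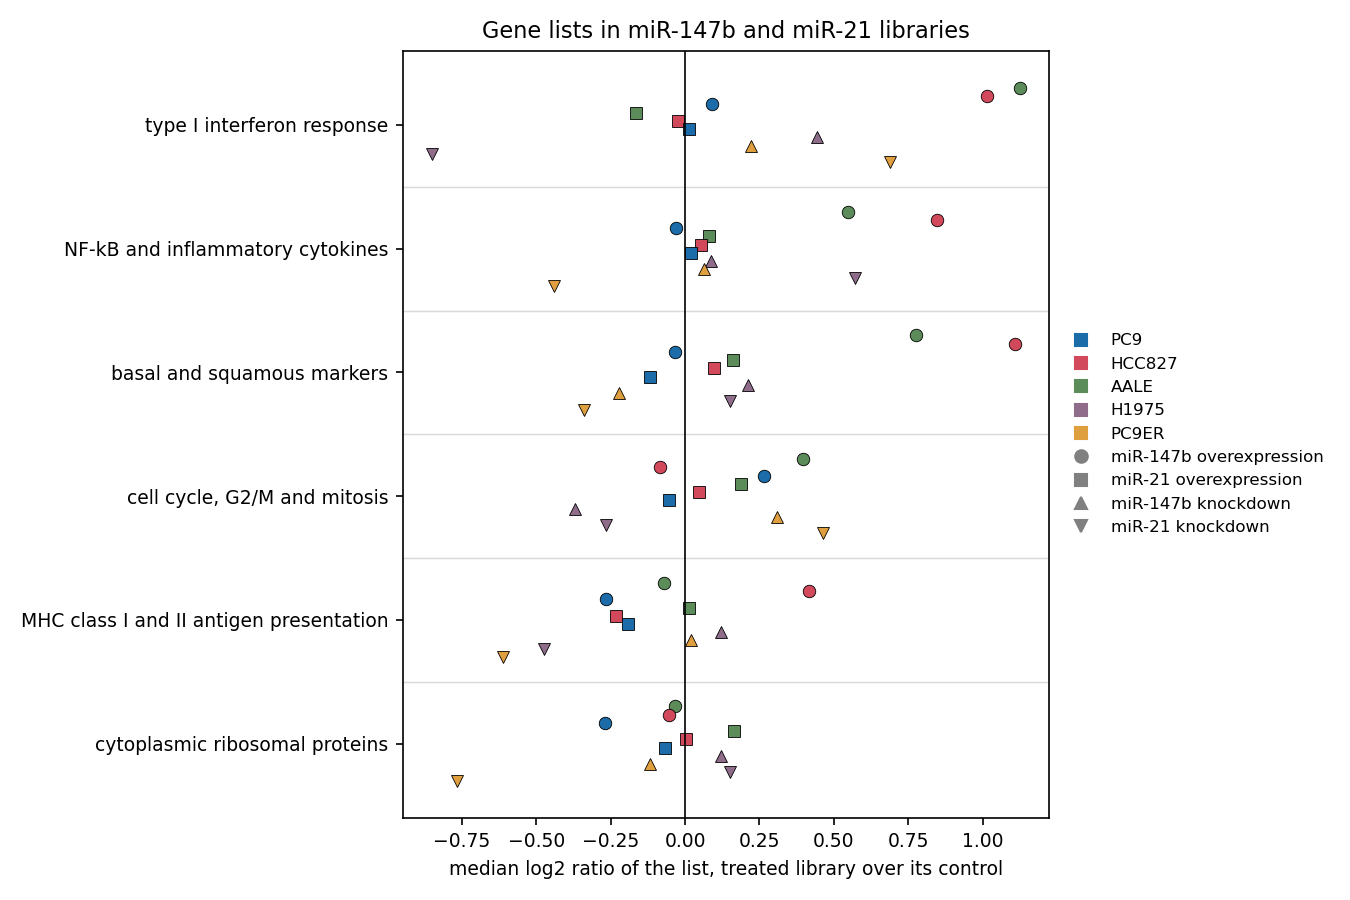
Median log2 ratio of 6 gene lists (y axis) in each overexpression or knockdown library over the control library of its line, with colours for the 5 lines and shapes for the miRNA and direction; each point is 1 library pair. The interferon list lies at 1.12 in AALE and 1.01 in HCC827 with miR-147b overexpression, at -0.85 in H1975 and at 0.69 in PC9ER with miR-21 knockdown.

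Knockdown of miR-147b left interferon genes higher in both lines. They were higher in 29 of 30 genes (median 0.41, camera adjusted p = 0.000129, adjusted p = 0.936 with an estimated correlation), with medians of 0.45 in H1975 and 0.22 in PC9ER. IFI27 went from 46.3 to 134 CPM in H1975 (1.29 ± 0.52, SE, n = 2 lines), and OAS3, a sensor of double-stranded RNA, had 0.43 ± 0.30. The fitted median turned to -0.26 and IFI27 to -0.07 without the miR-147b knockdown library of H1975. That fit also takes in the miR-21 knockdown libraries, and the list median of the PC9ER pair alone was 0.22. The small nucleolar RNAs SNORD49A, SNORD31 and SNORD43 had log2 fold changes of -4.92 ± 0.54, -4.63 ± 0.61 and -4.92 ± 0.65, SNORD49A going from 13.3 to 0.71 CPM in H1975 and from 139 to 3.14 in PC9ER. Genes annotated as small nucleolar RNA took 0.142% of counts in the PC9ER control library and 0.0223% in the H1975 control library. They took 0.00719% to 0.00796% in the knockdown libraries of either miRNA, so both controls stood above them, and 0.0208% or less in all others. EGFR had 0.40 ± 0.36 and VMP1 0.03 ± 0.25. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 17725 genes passed (146 at an unadjusted p under 0.05, smallest adjusted p 0.785). DESeq2 called 26, of which 22 are small nucleolar RNAs by biotype or symbol, and limma voom 0. Leaving out the control, miR-147b or miR-21 library gave 134, 61 and 13 genes for H1975 and 78, 36 and 18 for PC9ER, and no filter on low counts gave 28.

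Knockdown of miR-21 was accompanied by lower antigen presentation genes. All 20 MHC genes were lower (median -0.43, camera adjusted p = 7.71e-06, adjusted p = 0.950 with an estimated correlation). CD74, the invariant chain, stood at 72.8 and 44.2 CPM in control and miR-21 knockdown H1975 and at 119 and 32.8 in PC9ER (-1.27 ± 0.37, SE, n = 2 lines). HLA-DRB1, whose reads are shared with paralogs, had -1.79 ± 0.45. Ribosomal proteins (65 of 72 lower, median -0.28, camera adjusted p = 3.47e-05), glycolysis (18 of 20, -0.34, camera adjusted p = 0.00563) and epithelial markers (19 of 25, -0.27, camera adjusted p = 0.0385) were also called, each with adjusted p = 0.950 with an estimated correlation. The ribosomal and glycolysis medians became 0.08 and 0.03 without the miR-21 knockdown library of PC9ER. With a correction for gene length and GC content, the ribosomal, glycolysis and epithelial medians shrank to -0.04, -0.09 and -0.12 and were no longer called, while the MHC list, at -0.20, was. BCAT1, a branched-chain amino acid transaminase, went from 60.3 to 287 CPM in PC9ER and from 0.09 to 0.52 in H1975 (2.26 ± 0.36). The keratin KRT8 had -0.71 ± 0.33, the glycolytic PGAM1 -0.49 ± 0.31, IL1A 2.33 ± 0.60 and the interferon-induced GTPase MX1 -1.28 ± 0.52. SNORD49A and SNORD31 had -6.39 ± 0.58 and -6.99 ± 0.69. EGFR had 0.67 ± 0.37, VHL -0.31 ± 0.33 and SDHD 0.23 ± 0.30. In the PC9ER pair 60.1% of the variance of the log2 ratios across genes followed gene length and GC content, against 9.19% in H1975. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 17725 genes passed (357 at an unadjusted p under 0.05, smallest adjusted p 0.290). DESeq2 called 37, of which 29 are small nucleolar RNAs by biotype or symbol, and limma voom 0. Leaving out the control, miR-147b or miR-21 library gave 834, 84 and 5590 genes for H1975 and 71, 83 and 1 for PC9ER, and no filter on low counts gave 37. The fold changes of both knockdowns correlated across genes with r = 0.56 against a simulated 0.502, and the covariance differed by -0.0153.

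Overexpression and knockdown were set against each other for each miRNA, and a gene can differ here without moving oppositely in them. No line carries both, so these differences cannot be told apart from differences between the lines in their response. For miR-147b the difference was 2.78 ± 0.80 for the keratin KRT4 and -0.69 ± 0.22 for ASNS, asparagine synthetase (log2, SE, n = 3 lines with overexpression and 2 other lines with knockdown). S phase (median -0.25), ATF4 and unfolded protein response (-0.14) and ribosomal genes (-0.11) were lower and basal markers (0.72), NF-kB (0.21), G2/M (0.28) and interferon genes (0.38) higher, with camera adjusted p from 0.000193 to 0.0401 and adjusted p from 0.788 to 0.792 with an estimated correlation. The G2/M median turned to -0.13 without H1975. EGFR had -0.05 ± 0.52 and VMP1 0.04 ± 0.22. For miR-21, ABCG1, a sterol exporter, and BHLHE41, a circadian repressor, had 2.31 ± 0.53 and 1.40 ± 0.31. The membrane peptidase MME, FAM83B and the epithelial transcription factor EHF had -3.56 ± 0.56, -3.33 ± 0.56 and -2.26 ± 0.39. Ribosomal (0.28), glycolysis (0.34), MHC (0.31) and respiratory chain genes (0.17) were higher, with camera adjusted p from 2.92e-07 to 0.0182 and adjusted p = 0.918 with an estimated correlation. The ribosomal and glycolysis medians turned to -0.10 and -0.04 without PC9ER. EGFR had -0.72 ± 0.52, VMP1 -0.08 ± 0.22, VHL 0.26 ± 0.26 and SDHD -0.12 ± 0.26. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 20058 genes passed in either difference (318 and 862 at an unadjusted p under 0.05, smallest adjusted p 1 and 0.287). DESeq2 called 11 and 31, and limma voom 0 and 0. For miR-147b edgeR called 2 without PC9ER and 2 with no filter on low counts. For miR-21 it called 4098 without H1975 and 33 with no filter.

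Genes with a 3' UTR site for the miRNA seed were set against genes without one. For miR-147b the median of genes with a site lay -0.02 from that of other genes on overexpression (camera adjusted p = 0.202, adjusted p = 0.723 with an estimated correlation) and 0.01 from it on knockdown (camera adjusted p = 0.456). For miR-21 the difference was 0.02 on overexpression (camera adjusted p = 0.202), and on knockdown the 1304 genes with a site had a median of 0.35 against -0.07 in 12400 without (camera adjusted p = 3.1e-07, adjusted p = 0.723 with an estimated correlation). In single pairs of libraries, looked at after this result, that difference, between means, was 0.70 in PC9ER, where the median of 420 heptamers of the same bases was 0.71, and -0.05 in H1975. Against genes matched on 3' UTR length and expression, the miR-21 knockdown difference was 0.19 (camera adjusted p = 0.109), which did not pass, and for overexpression minus knockdown the medians were -0.36 and 0.03 (camera adjusted p = 4.73e-06, and 0.109 matched, adjusted p = 0.723 with an estimated correlation), and the same PC9ER library enters that difference.

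The genes that led tolerance were then followed into the miRNA libraries, which are other libraries with other controls. Neither the 100 genes highest nor the 100 lowest in tolerance to either drug were called with miR-147b overexpression (medians 0.02 and 0.07, camera adjusted p = 0.998 and 0.361) or knockdown (-0.06 and 0.04, camera adjusted p = 0.307 for both). The lowest set was lower with miR-21 knockdown in 76 of 97 genes (median -0.21, camera adjusted p = 0.00902) and higher for miR-21 overexpression minus knockdown in 72 of 98 (median 0.16, camera adjusted p = 0.00225), both with adjusted p = 1.00 with an estimated correlation. With 50 genes per direction neither was called (medians -0.205 and 0.163, camera adjusted p = 0.0796 and 0.0669). With 200 both were (medians -0.209 and 0.17, camera adjusted p = 0.00959 and 0.00124, adjusted p = 0.954 for both with an estimated correlation). Both contrasts take in the miR-21 knockdown library of PC9ER described above, whose log2 ratios followed gene length and GC content. Pearson correlations across genes with tolerance lay between -0.084 and 0.094, and genes are not independent replicates.

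Some lists were called in none of the 11 comparisons. EGFR ligands and receptors came nearest with miR-147b overexpression (17 of 22 higher, median 0.18, camera adjusted p = 0.0535), and p53 targets (18 of 25 lower, median -0.08, camera adjusted p = 0.0685), stem and ALDH persister markers (17 of 21 lower, median -0.06, camera adjusted p = 0.0786) and alveolar and airway secretory markers (12 of 15 lower, median -0.13, camera adjusted p = 0.105) with miR-21 overexpression. Neuroendocrine markers came nearest with miR-147b overexpression (6 of 10 lower, median -0.17, camera adjusted p = 0.325).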

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

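C15orf48, outside the rule for named genes, was chosen after its values were seen, and the other values below come from tests fixed beforehand or were not tested. The change with drug tolerance differed between HCC827 and PC9, by an interaction test, for 773 genes, and the values below are the change in HCC827 minus the change in PC9 on the log2 scale. The list medians were -2.83 for G2/M and mitosis, -1.63 for DNA replication and S phase, -1.91 for glycolysis, -1.18 for HIF targets, -1.83 for the interferon response, -1.51 for MHC genes, -1.95 for leukocyte markers, -1.19 for cholesterol genes, -0.67 for epithelial markers, -0.59 for NRF2 targets, -0.23 for the respiratory chain. They were 1.73 for mitochondrially encoded transcripts, 0.79 for NF-kB genes, 0.74 for mesenchymal markers, 0.60 for YAP/TEAD targets and 0.40 for reported miR-21 targets.

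Among single genes, lower values were found for the cell cycle genes PLK1 (-3.57), CCNB2 (-3.34), AURKA (-3.21), CDT1 (-3.71) and MCM4 (-1.87), for the interferon genes ISG15 (-3.90), IFIT1 (-3.90) and IRF9 (-2.91), for PSMB9 (-3.02) and TAP1 (-2.37) of antigen presentation. They were also found for NDRG1 (-4.03), BNIP3 (-2.77), EGLN3 (-4.41), PGK1 (-2.67) and LDHA (-2.20) of hypoxia and glycolysis. MUC1 (-3.01), TRIM31 (-6.87), CYP26A1 (-6.81), MYEOV (-6.63) and C15orf48 (-3.76) were lower too. Higher values were found for the YAP targets CTGF (5.90), ANKRD1 (2.91) and AMOTL1 (2.65), for HBEGF (6.61), CXCL2 (3.47), TNFAIP3 (2.92), CLDN1 (2.41) and MMP2 (4.26), and for MT-ND3 (3.74) and MT-ND1 (2.41). The spread in this test is that between the drugs, with 1 parental library per line, and edgeR called 0 genes without any 1 of the 4 tolerant libraries.

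In single pairs of libraries, some list medians lay in the highest 2.5% of random lists in 1 line and the lowest 2.5% in another, and these differences between lines were not tested. With miR-147b knockdown there were 6 lists, with medians in H1975 and PC9ER of -0.37 and 0.31 for G2/M, -0.41 and 0.42 for mitochondrially encoded transcripts, 0.27 and -0.30 for mesenchymal markers, -0.29 and 0.28 for cholesterol genes, 0.21 and -0.22 for basal markers and 0.12 and -0.12 for ribosomal proteins. With miR-21 knockdown there were 5, at -0.85 and 0.69 for interferon, -0.27 and 0.46 for G2/M, -0.48 and 0.90 for mitochondrially encoded transcripts, 0.67 and -1.03 for fibroblast markers and 0.15 and -0.77 for ribosomal proteins.

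With miR-147b overexpression there were 6, with medians in AALE, HCC827 and PC9 of 0.75, 0.31 and -0.44 for histones, -0.069, 0.42 and -0.27 for MHC genes, -0.11, 0.29 and -0.13 for epithelial markers, 0.33, -0.015 and -0.16 for glycolysis, -0.23, 0.15 and -0.15 for p53 targets and -0.12, 0.081 and -0.074 for ATF4 and unfolded protein response genes. With miR-21 overexpression there were 4, at 0.16, 0.10 and -0.12 for basal markers, 0.11, 0.072 and -0.16 for glycolysis, 0.16, 0.004 and -0.068 for ribosomal proteins and 0.093, -0.12 and 0.002 for ERK output genes. The PC9 medians with either miRNA share 1 scrambled library that stood apart. Its rRNA genes took 0.122% of counts, against 0.009% and 0.01% in the miR-147b and miR-21 libraries of PC9. RN7SK was at 206 CPM in it, against 9.37 and 10.7.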

How the results depend on the processing

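limma voom, the length and GC correction, and the fits without mitochondrially encoded genes, pseudogenes or small noncoding RNA genes were chosen after seeing the data, as was the estimated correlation for seed sites. Of the alternatives for list medians, 810 kept direction and, where the list was tested again, the call. Another 132 kept direction but lost the call and 18 turned. With DESeq2's Wald test and with limma voom no list was tested again, so the 88 medians of each count by direction alone. Fry and camera with an estimated correlation are not in this tally and are given below. Of the alternatives for named genes 1382 kept direction and call, 251 gained a call, 150 lost one and 47 turned. The cause was not tested, except that a fit without a library has fewer samples. In tolerance and knockdown, with 2 lines, a fit without a parental, control or treated library sees that group in 1 line alone. How the lines differ in that change then no longer enters the spread. Gene counts from such fits are therefore not calls replicated over lines. Where a left-out library leaves a group with 1, that library is assumed to vary like the others. In the self-test, depth and replication gave few calls of log2 size 1 in tolerance and knockdown. No scaling moved the median of all genes by over 0.1. It was 0.169 against 0.0404 for tolerance to either drug with no filter, over 36132 genes in place of 19837.

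Genes called were 0 by edgeR and 1346 by DESeq2 for gefitinib tolerance, 0 and 1761 for osimertinib, 0 and 2478 for either drug, 0 and 7 for osimertinib against gefitinib. They were 773 and 2347 by cell line, 1 and 7 for miR-147b overexpression, 0 and 1 for miR-21 overexpression. They were 0 and 26 for miR-147b knockdown, 0 and 37 for miR-21 knockdown, and 0 and 11, and 0 and 31, for overexpression minus knockdown of miR-147b and miR-21. With no filter on low counts these were 47, 137, 541, 0, 3, 263, 76, 28, 37, 2 and 33. limma voom called 4 for miR-147b overexpression, 628 by cell line and 0 elsewhere. The pairing of libraries by line was the block, and with no replicate block miR-147b overexpression called 0, as it did with all 15 miRNA libraries in 1 fit. No block was not run by cell line, and the fit of 15 covers overexpression and knockdown alone. Neither moved another gene count. Without mitochondrially encoded genes the count by cell line was 841 (737 shared), without pseudogenes 834 (732 shared) and with DESeq2 size factors 816 (762 shared).

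With libraries or lines left out, counts ran from 0 to 3571 for gefitinib tolerance (3571 without parental PC9), 0 to 3976 for osimertinib (3976 without parental PC9), 2 to 4584 for either drug (4584 without parental PC9). They ran from 0 to 3 for osimertinib against gefitinib (3 without gefitinib-tolerant HCC827) and 0 to 0 by cell line, 0 to 5 for miR-147b overexpression (0 without AALE, 5 without PC9). In knockdown they ran from 13 to 134 for miR-147b knockdown (134 without control H1975), 1 to 5590 for miR-21 knockdown (5590 without miR-21 knockdown H1975) and for the differences from 0 to 2 for miR-147b overexpression minus knockdown (2 without PC9ER) and 0 to 4098 for miR-21 (4098 without H1975). The other libraries that move these counts are named in the report. Tolerance by cell line has no value without parental replicate 1 or parental replicate 2, since a line then has no control.

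Over all contrasts 88 lists were called, 0 with an estimated correlation and 4 by fry. Of the tolerance sets 2 were called, 0 with 50 genes, 2 with 200 genes and 0 with an estimated correlation. Of the seed site tests 2 were called, with 2 for 8mer sites, 0 with matched genes and 0 with an estimated correlation. List medians ran, with a library or line left out, from -0.71 to 0.31 for HIF, -0.84 to 0.29 for glycolysis, -0.23 to 0.51 for YAP/TEAD and -0.47 to 1.27 for G2/M in osimertinib against gefitinib. They ran from -1.48 to 0.37 for interferon with gefitinib and -1.41 to 0.39 with either drug, from -1.52 to 0.23 for HIF with osimertinib, and from -0.26 to 1.02 for interferon with miR-147b knockdown. With miR-21 overexpression they ran from -0.004 to 0.14 for HIF and -0.067 to 0.089 for ribosomal genes (-0.01 with no filter). They ran with miR-21 knockdown from -0.69 to 0.077 for ribosomal and -0.79 to 0.028 for glycolysis genes, for miR-21 overexpression minus knockdown from -0.10 to 0.67 and -0.037 to 0.67, and for G2/M in miR-147b overexpression minus knockdown from -0.13 to 0.60.

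Genes near 0 turned most. EGFR ran from -0.17 to 0.65 with miR-147b overexpression (-0.10 without the block), -0.032 to 0.91 with its knockdown, -0.57 to 0.26 for their difference and -0.26 to 0.069 by cell line. VHL ran from -0.51 to 0.018 with osimertinib, -0.13 to 0.13 with either drug (0.023 without mitochondrially encoded genes). It ran from -0.30 to 0.50 by cell line, -0.05 to 0.074 with miR-147b overexpression (-0.002 by DESeq2, -0.001 with DESeq2 size factors), -0.15 to 0.27 with miR-147b knockdown (-0.008 with the length and GC correction). It ran from -0.12 to 0.045 with miR-21 overexpression, -0.68 to 0.042 with miR-21 knockdown, -0.10 to 0.029 for miR-147b overexpression minus knockdown and -0.081 to 0.56 for miR-21. SDHD ran from -0.28 to 0.085 with gefitinib, -0.35 to 0.018 for osimertinib against gefitinib, -0.014 to 0.27 with miR-147b overexpression, -0.15 to 0.24 with its knockdown (-0.009 with the correction). It ran from -0.044 to 0.24 for their difference, -0.028 to 0.48 with miR-21 knockdown (-0.13 with the correction) and -0.51 to 0.21 for miR-21 overexpression minus knockdown. VMP1 ran from -0.058 to 0.39 for osimertinib against gefitinib, -0.043 to 0.24 with miR-147b overexpression, -0.052 to 0.096 with its knockdown (-0.059 with the correction), -0.066 to 0.22 for their difference and -0.27 to 0.075 for miR-21, and was -0.12 with miR-21 knockdown and the correction. IFI27 ran from -0.065 to 1.66 with miR-147b knockdown.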

Other observations

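The tests of miR-147b dose in both directions, of 8 families of RNA without a poly(A) tail, of reads moved between histone genes, of length and GC content and of H1975 RNA, the ranking of seeds in single pairs and the choice of C15orf48 were made only after the result was seen. C15orf48 (chromosome 15, 45430529 to 45448761, GRCh38), the host of MIR147B, encodes a small mitochondrial protein. It stood at 19.4 CPM in parental PC9 and at 187.5 and 191.5 CPM in its gefitinib-tolerant and osimertinib-tolerant libraries, 9.67- and 9.87-fold more, and at 11.1, 6.52 and 9.47 CPM in HCC827. The scrambled control library of PC9, for which the labels give no drug, stood at 175 CPM, near the tolerant level, so this rise rests on 1 low parental library. The log2 difference between the lines, HCC827 minus PC9, which rests on that library too, was -3.76 ± 0.36 (SE), at an adjusted p of 0.0333 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With miR-147b overexpression C15orf48 went from 1.82 to 251 CPM in AALE and from 2.49 to 190 in HCC827, and from that 175 to 156 in PC9, and how these reads divide between the vector and the gene is unknown. In PC9ER it stood at 296 CPM in the control, 248 in the miR-147b knockdown and 95.7 in the miR-21 knockdown library, and in H1975 at 50.3, 60.8 and 63.9.

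In single pairs of libraries, which carry no test, IGFBP7, a secreted binding protein, stood at 0 CPM in parental and 59.7 in gefitinib-tolerant HCC827, and the basement membrane collagen COL4A3 at 0.05 in parental and 33.5 in osimertinib-tolerant HCC827. In PC9, the neuropeptide GAL stood at 55.9 and 2.93 CPM and the kinase DCLK1 at 63.1 and 5.71 CPM in parental and gefitinib-tolerant cells. With miR-147b overexpression, the imprinted RNA H19 stood at 17.8 and 155 CPM and LCN2, an iron-binding secreted protein, at 113 and 35.4 CPM in AALE, and with its knockdown the complement gene C3 stood at 9.43 and 94.1 CPM in H1975. Ranked from the lowest among heptamers of the same bases, genes with a miR-147b seed site lay at 2, 12 and 75 of 105 in PC9, HCC827 and AALE with overexpression and at 28 and 102 in PC9ER and H1975 with knockdown. Those with a miR-21 seed site lay at 149, 250 and 342 of 420 and at 181 and 334. With 3' UTR length, gene length and GC content regressed out, these ranks became 2, 11, 80, 50 and 102 for miR-147b and 233, 345, 344, 312 and 316 for miR-21.

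Interferon genes had higher values with miR-147b overexpression, with list medians at percentile 100 of random lists in 2 of 3 lines, AALE and HCC827, and 87.0 in PC9, which argues against 1 cell line alone. Each line has 1 library pair, and random lists do not move together as interferon genes may, so the percentiles do not exclude differences between single libraries. The same list lay at -0.85 in H1975 and at 0.69 in PC9ER with miR-21 knockdown. The median in the miR-21 libraries was -0.042 of that with miR-147b, so the list did not rise with the miR-21 construct over the same control. This cannot test a response to lentiviral transduction shared by all constructs, because the scrambled control would cancel it in both medians. How far transduction differed between libraries was not measured. MIR21 had 0 counts, so the miR-21 construct itself could not be checked. The direct contrast of miR-147b with miR-21 reuses the same miR-147b libraries and is not separate evidence. In it all 30 genes were higher (median 0.95, camera adjusted p = 7.92e-44, adjusted p = 0.280 with an estimated correlation). A dose effect of miR-147b in both directions cannot be told apart, because the knockdown could not be checked: the lower of its medians, in PC9ER, was 0.222 and not negative. The fitted median turned from 0.41 to -0.26 without the miR-147b knockdown library of H1975. That fit also takes in the miR-21 knockdown libraries, so its sign differs from that of the PC9ER pair alone. An effect of the construct in AALE and HCC827, whether of the miRNA or of other parts of it, remains open as a candidate explanation, as do differences between single libraries.

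Replication-dependent histones had higher values in tolerant cells of both lines although S phase genes had lower ones. Carry-over of RNAs without a poly(A) tail was gauged by 8 families of such RNA. Some had few counts in single libraries (RMRP 4 and U4 3 in gefitinib-tolerant HCC827). The family median log2 ratio ran from -2.45 in that library to 2.26 in gefitinib-tolerant PC9, so the families are no steady gauge. As far as they gauge it, carry-over is argued against in 3 of the 4 tolerant libraries. There the median of the families was at most 0.029 of the histone median, with 1 family (RMRP, 8 and 13 counts, in osimertinib-tolerant PC9) at 0.5 of it or more. In gefitinib-tolerant PC9 their median was 1.33 of it (7SK 550 to 3324 counts, RPPH1 61 to 530, RMRP 8 to 906) and small noncoding RNA went from 0.0720% to 0.165% of counts, so carry-over may be a source there, and the median of 222 short noncoding RNA genes, at most -0.136 of the histone median, decides nothing at median counts of 11 to 21. Reads moved between near-identical histone genes would leave the sum of all 88 such genes unchanged: it was higher by 1.18 or more (log2) in HCC827, which argues against it, while in PC9, at 0.469 and 0.472, it cannot be told apart, because that lies under the bound of 0.5 set for it. Polyadenylated histone transcripts of cells leaving the cycle cannot be told apart. The 5 members known for polyadenylated forms differed from the other 13 by -0.263 (means 1.44 and 1.70, exact permutation test, two-sided p = 0.620). That lies within the spread of single members, whose values are uncertain because they share reads. A change in histone genes with tolerance stays open too and may apply to HCC827.

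In PC9ER, 923 genes stood over 1 log2 from the control in both knockdown libraries, 736 of them higher, against 328 in H1975. In each line both ratios share 1 control library, which alone can put genes over 1 log2 in both. How many it would put there was not computed. Knockdown of the miRNAs as the cause cannot be told apart, because neither knockdown could be checked, although in H1975 the same genes had a median change of -0.037 of that in PC9ER and 40.0% shared the sign. RNA of H1975 cells is argued against by 5 genes of H1975 that PC9 lacks, whose median level was 0 percent of that in H1975. A trend with gene length and GC content explained at least 24.1% of the variance between the PC9ER control and knockdown libraries (60.1% with miR-21 knockdown), against 2.49% and 9.19% in H1975, and may be a source. The miR-21 knockdown library stood apart from the other PC9ER libraries, with standard deviations of log2 ratios of 1.17 and 0.928, while the control and miR-147b knockdown libraries, at 0.402, lay near the 0.326 to 0.357 of H1975.

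Of the 10 splits of the 6 libraries with miR-147b overexpression, 1 called as many genes as the real split (1 gene, with 0 as the highest of the others), and 3 splits, the real one among them, called as many lists (13 in the real split, 15 at most in the others). The 4 splits that part all 3 line pairs were fitted with the line as a block, where the others called 12, 9 and 6 lists, and the 6 other splits without it, where 14 and 15 were the highest. With miR-21 overexpression the real split called 0 genes, so all 10 splits reach it and decide nothing (19 at most in the others). For lists 6 splits, the real one among them, called as many (8 in the real split, 13 at most in the others), and of the splits with the block the others called 12, 4 and 3. For both miRNAs 10 splits are too few for a share under 0.05.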
